A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 36 samples.

How the data were processed

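RNA was measured by sequencing in Synechococcus elongatus, a unicellular cyanobacterium, in 36 libraries from 18 groups of 2. Per the labels' protocols, cultures of the wild type and of a rel- strain were grown in BG11 medium at 30 °C under cycles of 12 h light at 40 µE and 12 h dark, and cells were collected at dusk and after 5, 15 and 30 min and 1, 2, 4, 8 and 12 h of darkness. The headers of the deposited table call the mutant spoT- where the titles call it rel-. Rel is the enzyme that makes the alarmone ppGpp in this organism. Per the labels' protocols, external RNA standards were present in the lysis buffer, ribosomal RNA was depleted with a Ribo-Zero kit, and stranded TruSeq libraries were sequenced on a HiSeq instrument. Whether the 2 replicates of a group were separate cultures is not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

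The authors deposited 1 table with 2715 loci and 1 signal value per locus and library. Bowtie 0.12.7 is named per the submitters' processing notes. The counter, the strand setting, the genome build and the annotation are not given in the sources used here, so reads shared by overlapping, antisense or near-identical loci could be assigned in ways that cannot be followed. The deposited signal values were found to be whole reads times a single factor per library: 100% of the values in every library were whole multiples of its factor within 0.01 reads. The factors ran from 0.760 to 6.71, with 1 for the wild type dusk replicate 1 library. How the authors computed the factors is not given in the sources used here, and 0 rows of the table are named as external standards, so the link between the standards and the factors could not be checked. Any comparison of absolute signal between libraries rests on these factors. The recovered depth was 2001839 to 15209517 reads per library, with a median of 7274046. Between 12 and 65 loci had 0 reads in a library, and 3 reads, the limit that a count of 0 allows, corresponded to a signal of 2.28 to 20.1. These limits cover counting error only, since reads amplified by PCR are not independent molecules. Replicates were compared by chi-square over loci with at least 20 reads in a pair. The statistic per degree of freedom was 81.7 to 791, so every pair differed by far more than sampling noise and was counted as 2 samples.

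The loci are identified by tags. The reference table matched 0 of the 2715 tags, so the files do not pair tags with gene names, and 0 of the 27 gene lists fixed before the data were examined could be matched or tested. The rule for named genes, also fixed then, took named genes with the largest changes among those past the threshold that moved the same way in both same-numbered replicates. Because no tag had a name, the same size order was applied to tags, and at most 2 that rose and 2 that fell are given per comparison. The tag Synpcc7942_1377 had been fixed beforehand as the rel locus, and no source used here pairs that tag with the name. Loci with the prefixes R and B in their tags were grouped after seeing the data. The meaning of the prefixes is not given in the table.

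Values were analysed as log2(value + 31.2), where the pseudocount is the 5th percentile of the positive values, so fold changes are on that scale and understate the change of low loci. A locus was kept if at least 2 libraries reached the 10th percentile, 62.5, which left 2692 loci and left out 23. The main test was limma 3.58.1 with a mean-variance trend in R 4.3.3, with 18 group means, all 36 libraries, and Benjamini-Hochberg adjustment at 0.05. The change in darkness within a strain was a joint F-test of 8 dark times against dusk, as was the difference between the strains' responses. Loci past an F-test were counted as higher or lower by the sign of the mean over the dark times, which the F-test does not test. For named loci in these comparisons, the change and SE are of that mean, and the adjusted p is of the F-test. The strains were compared in darkness on the mean log2 value of each of the 4 time courses, 2 against 2, because libraries of a time course may come from a shared culture. At dusk and at single times the strains were compared with the spread pooled over all 36 libraries. Libraries of a course deviated together, so those p-values may be too small. Summed signal per library was compared by exact permutation over the 4 courses. Prefix groups were tested with camera, which compares a group with the other loci, at a preset correlation of 0.01 and with an estimated correlation, and with fry, which tests whether a group moves on balance in a direction. Their p-values were adjusted over both groups and all contrasts together, except that those on the course means were adjusted over both groups alone.

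A count test was planned only for raw counts, and the deposited signal is not raw, so limma was the main test. The alternatives were centring of each library on its median, quantile normalization, other pseudocounts, no filter, limma without the trend or with robust moderation, a replicate block, culture as a random effect, fewer libraries in the fit, a minimum of 2-fold, the strain comparison by a joint F-test or from 1 h on, the difference in response on course means, sums without the 20 highest loci, medians in place of sums, and leaving out each library and each time course. These were chosen before the data were examined. Chosen after seeing the data were edgeR 4.0.16 on the recovered whole reads with the deposited factors and with TMM, a replicate block within each strain, fits without the 12 h time and without the 4 h and 8 h times, sums without R-prefixed loci, the prefix groups and their test on the course means.

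The procedure was tested on simulated data with 200 changed loci. The simulation gave all loci 1 spread and used the wild type dusk level in every group, without a shared shift. A changed locus moved by the same step in every library of the changed groups, and loci low at dusk were not among the changed ones. The shares below hold for that setting and may differ in the real data, where far more loci passed. For wild type darkness against dusk, run on 2582 loci, it recovered 1.47% of 2-fold, 56.1% of 4-fold and 100% of 16-fold changes. The same shares were 2.94%, 68.2% and 98.5% for rel- darkness against dusk on 2580 loci, 14.7%, 80.3% and 100% for the strains at dusk on 2579 loci, and 44.1%, 100% and 100% for the strains in darkness on 2591 loci. For the difference in the dark response, on 2581 loci, they were 0%, 4.55% and 97.0%. In these simulations limma also called 7 unchanged loci for the strains at dusk, 7 for the strains in darkness and 0 in the other comparisons. With no change simulated, limma called 0 loci in each of the 5 comparisons. In unchanged data edgeR, fitted over all libraries, called 441 of 2573 loci for the strains in darkness and 0 in the other 4 comparisons.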

Results

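Transcript levels were followed from dusk through 12 h of darkness in wild type S. elongatus and in the rel- strain, which was compared with it to ask how Rel shapes gene expression when the light goes off. The 9 times in 2 strains gave 18 groups of 2 libraries. Wild type libraries held 2001839 to 9864797 reads and rel- libraries 2822351 to 15209517. Values are the authors' deposited signal, reads times a factor per library whose origin is not given in the sources used here.

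The locus fixed beforehand as rel, Synpcc7942_1377, was examined in every library to check the labels. Its signal was 4749 to 8871 in the 18 wild type libraries and 0 to 346 in the 18 rel- libraries. In reads, these ranges were 1749 to 9141 and 0 to 69. The rel- replicate 1 libraries held 0 to 14 reads at this locus and the replicate 2 libraries 5 to 69. Every library thus lay on the side its label gives.

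In wild type cells most loci past the threshold were lower in darkness on the deposited scale. At 5 min the median locus had changed by -0.50 on the log2 scale, at 1 h by -1.62 and at 12 h by -1.72. The locus with the largest rise, Synpcc7942_2401, rose by 5.49 ± 0.91 (log2, SE; limma adjusted p = 0.000331), from a signal of 721 ± 258 at dusk to 39636 ± 48227 at 12 h (SD, n = 2), so its 12 h replicates disagreed. Synpcc7942_0781 rose by 4.86 ± 0.70 (limma adjusted p = 0.00024). Synpcc7942_1439 fell by 5.69 ± 0.69 (limma adjusted p = 1.94e-07), from 41313 ± 1749 to 169 ± 37.9 (SD, n = 2), and Synpcc7942_1488 fell by 6.02 ± 1.46 (limma adjusted p = 0.000281), to a 12 h signal of 17.1 ± 19.2 (SD, n = 2) that is near the signal of a few reads. These changes are means over the 8 dark times minus dusk, while their adjusted p-values are of the joint F-test. Of 2692 loci, 1696 passed the joint F-test, 107 higher and 1589 lower by the sign of that mean. With each library centred on its median, 1028 passed, 634 higher and 394 lower. Centring sets the shift that loci share to about 0 by construction, so it does not test that shift. Leaving out the wild type replicate 1 course lowered the count to 462 and leaving out the replicate 2 course lowered it to 551.

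The 45 B-prefixed loci had a median change of -0.74 in wild type darkness, against -1.42 for the 2605 loci without a prefix. After centring these medians were 0.78 and 0.10, so the group's direction turns with the scaling. Over the mean of the dark times, 4 B-prefixed loci were higher, 21 lower and 20 not past the threshold. Camera placed the group above the other loci (adjusted p = 0.00117), but this call was lost (adjusted p = 0.17 with an estimated correlation). Fry, which does not compare the group with other loci, found it lower on balance as deposited (adjusted p = 0.0016) and higher after centring (adjusted p = 5.25e-05). In rel- darkness the B-prefixed median was -0.45 (camera adjusted p = 0.000109; adjusted p = 0.132 with an estimated correlation) and after centring 0.74. Fry found the group lower as deposited in rel- (adjusted p = 0.0102) and higher after centring (adjusted p = 0.000399). The 42 R-prefixed loci had a median change of 0.37 in wild type, 1.90 after centring, and 39 of them did not pass the threshold. In rel- the median was 0.12 (camera adjusted p = 4.43e-10; adjusted p = 0.222 with an estimated correlation) and after centring 1.32. The wild type camera call (adjusted p = 2.75e-13) was also lost (adjusted p = 0.17 with an estimated correlation). The median R-prefixed locus differed between wild type replicates by up to 4.00 on the log2 scale, at 12 h, so no direction is drawn for this group.

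**Figure D1:**
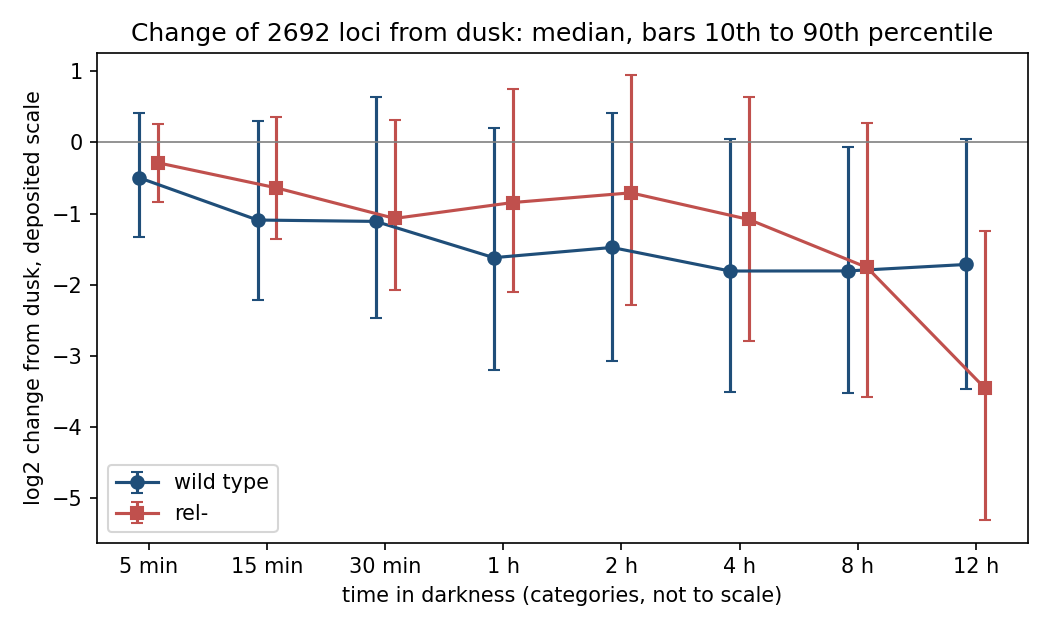
Median log2 change from dusk of 2692 loci at each dark time on the deposited scale, for wild type (circles) and rel- (squares), with bars from the 10th to the 90th percentile of loci. The wild type median reached -1.62 at 1 h, while the rel- median was -0.84 at 1 h and -3.46 at 12 h.

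In the rel- strain the median locus changed by -0.29 at 5 min, -0.84 at 1 h, -1.76 at 8 h and -3.46 at 12 h. Synpcc7942_2401 rose by 4.80 ± 0.91 (limma adjusted p = 0.00594) and Synpcc7942_0253 by 3.75 ± 0.64 (limma adjusted p = 0.000813), the latter from 12819 ± 4084 at dusk to 202867 ± 34740 at 12 h (SD, n = 2). Synpcc7942_0829 fell by 5.31 ± 0.43 (limma adjusted p = 4.89e-09), from 7244 ± 7331 at dusk, where the replicates disagreed, to 69.2 ± 10.1 at 1 h (SD, n = 2). Its mean change was -3.77 in replicate 1 and -6.85 in replicate 2, a gap that the SE, pooled over 18 groups, does not show. Synpcc7942_1488 fell by 5.06 ± 1.46 (limma adjusted p = 0.000921), and its rel- dusk signal was 110767 ± 153147 (SD, n = 2). After quantile normalization this locus no longer passed (limma adjusted p = 0.0546; 0.000921 on the deposited scale). In all, 2459 loci passed the joint F-test, 266 higher and 2193 lower by the sign of the mean over the dark times. That mean itself passed at 1812 loci, 88 higher and 1724 lower. After centring 1284 passed the F-test, 653 higher and 631 lower. Between 8 h and 12 h, 2169 loci fell in rel-, and the median change over all 2692 loci was -1.72. In wild type 0 loci passed, and the median change was 0.08. This contrast was not part of the plan and was run on the deposited scale alone, so it rests on the factors.

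The dark responses of the strains were then set side by side. Across 2692 loci the mean dark changes had Pearson r = 0.80 and Spearman rho = 0.76. With replicate 1 alone r was 0.73 and with replicate 2 alone 0.74, and at single times it was 0.68 at 8 h and 0.69 at 12 h. Loci are not independent replicates, so no p is given. No library entered both responses. After centring, 381 loci past the joint F-test in both strains had a higher mean in both, where independent lists would share 154. Another 263 had a lower mean in both, where they would share 92.4. Another 34 were higher in wild type and lower in rel-, and 22 the reverse.

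At dusk nearly all loci had higher deposited signal in rel- than in wild type. The median difference was 2.52 on the log2 scale, or 5.75-fold. Synpcc7942_2600 was higher by 5.73 ± 0.67 (limma adjusted p = 2.84e-07), with a signal of 12982 ± 5871 in rel- and 220 ± 133 in wild type (SD, n = 2). Synpcc7942_2601 was higher by 5.63 ± 0.70 (limma adjusted p = 4.53e-07). The single lower locus among those past the threshold was Synpcc7942_1377. Of 2692 loci, 2475 passed, 2474 higher and 1 lower. The spread was pooled over libraries that deviated together within a course, so the dusk p-values may be too small. After centring, 158 passed, 75 higher and 83 lower, and Synpcc7942_2600 was still higher, by 3.18 (limma adjusted p = 0.00774). B-prefixed loci had a median difference of 0.91 against 2.55 for loci without a prefix, and camera placed them below the other loci (adjusted p = 1.89e-28; adjusted p = 0.000256 with an estimated correlation). Of the 45, 18 were higher, 0 lower and 27 not past the threshold, and after centring their median was -1.64 (camera adjusted p = 0.000969 with an estimated correlation). The R-prefixed median was 1.64, and -0.91 after centring, with 7 of 42 loci higher as deposited (camera adjusted p = 7.65e-26; adjusted p = 0.072 with an estimated correlation).

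**Figure D2:**
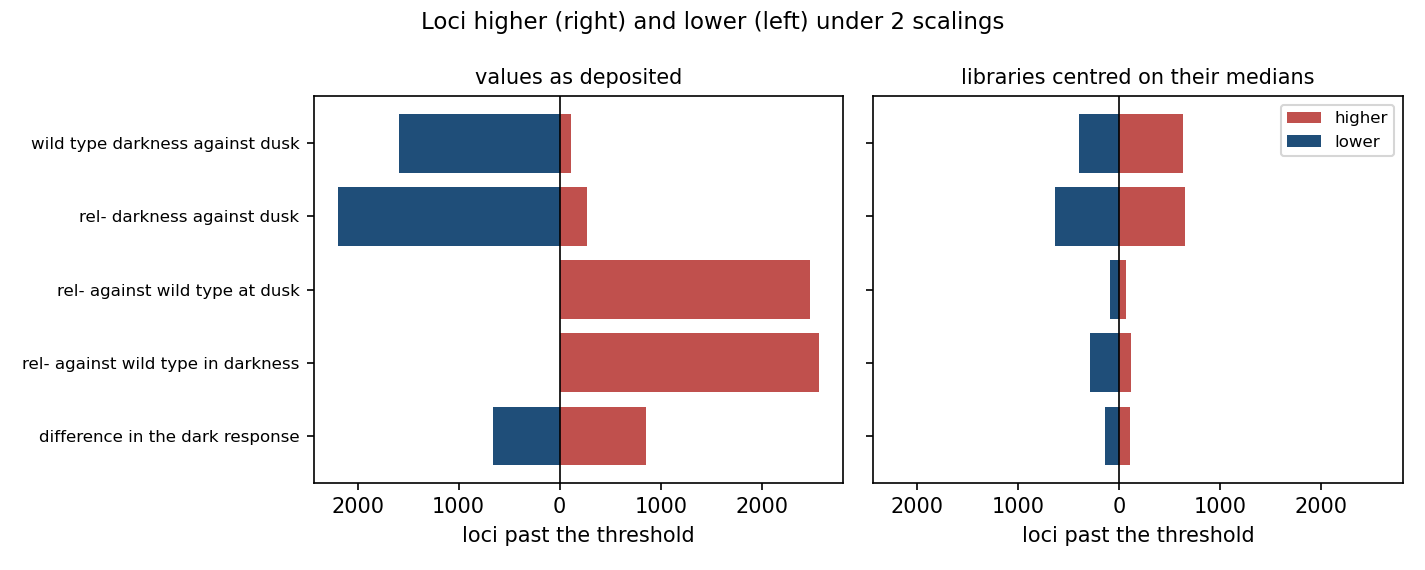
Number of loci past the threshold in each of 5 comparisons, higher to the right and lower to the left, with the values as deposited and with each library centred on its median. Where the test was a joint F-test, the side is the sign of the mean over the dark times. At dusk the counts are 2474 higher and 1 lower as deposited and 75 higher and 83 lower after centring.

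In darkness the median over loci of the rel- minus wild type course means was 2.69, or 6.44-fold. By time the median was 3.30 (9.85-fold) at 1 h and 0.85 (1.80-fold) at 12 h. At 12 h 1002 loci passed, 910 higher and 92 lower, and after centring 849 did, 368 higher and 481 lower. Synpcc7942_2328 was higher in rel- by 6.29 ± 0.37 and Synpcc7942_0669 by 6.15 ± 0.35 (limma adjusted p = 3.99e-05 for each). After centring these differences were 3.40 and 3.26 (limma adjusted p = 0.0075 for each). At 8 h the signal of Synpcc7942_0669 was 19128 ± 4900 in rel- and 41.4 ± 0.805 in wild type (SD, n = 2). Synpcc7942_2419 was lower by 2.67 ± 0.33 (limma adjusted p = 8.33e-05), and its difference after centring was -5.56 (limma adjusted p = 0.000286). Of 2692 loci, 2570 passed, 2568 higher and 2 lower. After centring 408 passed, 119 higher and 289 lower. On the course means the 45 B-prefixed loci had a median difference of 0.88, against 2.71 for loci without a prefix, and 29 were higher, 0 lower and 16 not past the threshold. Camera placed them below the other loci (adjusted p = 1.05e-26; adjusted p = 0.0483 with an estimated correlation), and after centring the call was lost (adjusted p = 0.102 with an estimated correlation). The R-prefixed median was 1.36 and -1.52 after centring, with 18 of 42 loci higher as deposited (camera adjusted p = 2.53e-31; adjusted p = 0.118 with an estimated correlation). The group tests on course means were added after seeing the data, and their p-values were adjusted over both groups of that contrast alone.

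The strains' responses to darkness were compared directly. The signal of Synpcc7942_2328 was 718 ± 209 at dusk and 193 ± 112 at 2 h in wild type, and 6872 ± 1833 and 31435 ± 9186 in rel- (SD, n = 2). Its response differed by 3.08 ± 0.56 (limma adjusted p = 0.000149). For Synpcc7942_0908 the difference was 2.90 ± 0.48 (limma adjusted p = 5.87e-05). Synpcc7942_1254 went the other way, by -2.95 ± 0.49 (limma adjusted p = 1.89e-05): its signal was 1270 ± 8.72 at dusk and 4986 ± 1505 at 30 min in wild type, and 54234 ± 16226 and 29342 ± 5656 in rel- (SD, n = 2). Synpcc7942_0494 differed by -2.79 ± 0.90 (limma adjusted p = 0.00107). These p-values are of the joint F-test over the dark times, not of the mean differences they follow. In all, 1508 loci passed the joint F-test, 849 higher and 659 lower by the sign of the mean over the dark times. The F-test does not test that mean, which itself passed at 14 loci, 9 higher and 5 lower. After centring 249 passed the F-test, 113 higher and 136 lower, and the mean passed at 112, 27 higher and 85 lower. With the dark times averaged per course 91 passed, and the F-test with culture as a random effect called 2311. The majority by sign turned with the pseudocount, to 664 higher and 930 lower at the 20th percentile. Camera did not set B-prefixed loci apart in this difference (adjusted p = 0.927), and its call for R-prefixed loci (adjusted p = 0.0186) was lost (adjusted p = 0.67 with an estimated correlation). At 2 h 31 loci differed as deposited, 31 higher and 0 lower in rel- relative to wild type, and 35 after centring, 14 higher and 21 lower. At 4 h 129 did, 124 higher and 5 lower, and after centring 142, 53 higher and 89 lower. The count at 2 h was 56 with the pseudocount at the 1st percentile, and that at 4 h was 72 at the 20th. The replicate block and culture as a random effect raised the counts at 2 h and 4 h more, as given below. At 12 h alone 1205 did, 19 higher and 1186 lower, and after centring 331, 135 higher and 196 lower. Without the 12 h time, a fit added after seeing the data, the joint test called 99 loci, and 152 after centring. As deposited it called 790 without the wild type 12 h replicate 2 library, 887 without the rel- 12 h replicate 2 library, 204 without the wild type replicate 1 course and 1 without the wild type replicate 2 course.

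The summed signal per library was higher in rel- at all 9 times. At dusk it was 49275166 ± 4718930 in rel- and 9437410 ± 604416 in wild type (SD, n = 2), a ratio of 5.22 ± 0.60. At 12 h it was 10731485 ± 45559 and 7018986 ± 931564, a ratio of 1.53 ± 0.20. Reads at dusk were 7722245 ± 167185 in rel- and 8094957 ± 2502932 in wild type, so the dusk ratio comes from the factors, with means of 6.38 and 1.21. The exact permutation test over 4 courses gave a two-sided p of 0.333 at dusk and in darkness, the smallest this design allows. A single locus, Synpcc7942_R0017, took 23.1% ± 2.07 of wild type and 8.66% ± 0.457 of rel- reads at dusk, and 47.9% ± 5.00 and 30.6% ± 2.74 at 12 h (SD, n = 2). It was singled out after its values were seen.

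**Figure D3:**
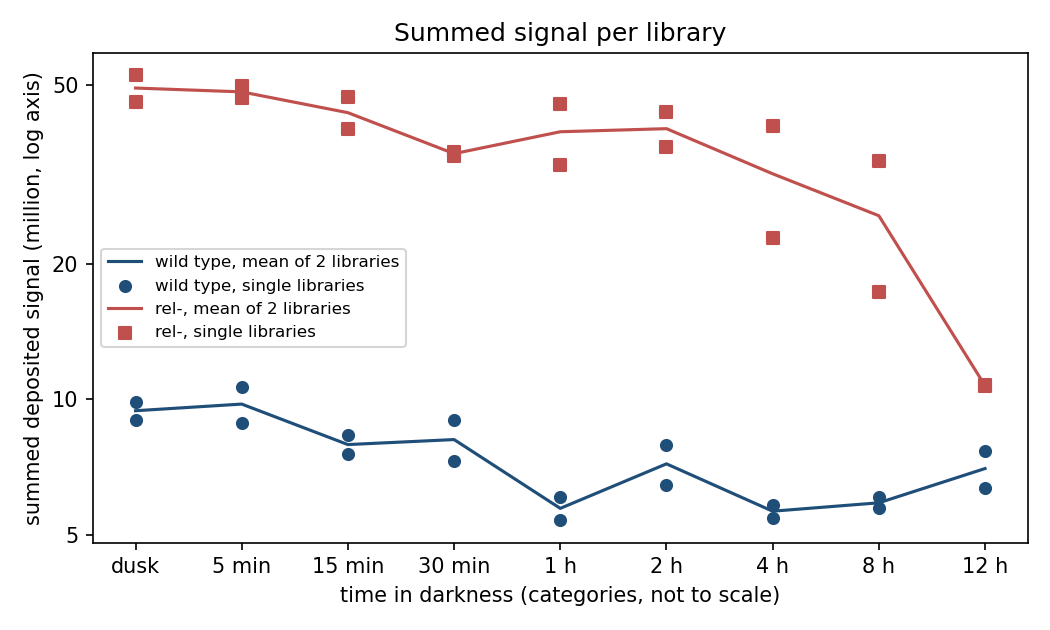
Summed deposited signal per library on a log axis, against time in darkness, with points for single libraries and lines for the means of 2. The rel- libraries lie above the wild type libraries at all 9 times, and their replicates are far apart at 4 h (22878926 and 40646880) and 8 h (17319077 and 33929698).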

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

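Centring and the sums without the 20 highest loci were planned before the data were examined, but their bounds were set after the results were seen. The tests on single multipliers and on R-prefixed loci were chosen after the results were seen, and the test on read numbers before. The response to darkness differed between the strains at 1508 loci by the interaction F-test, at 249 loci after each library was centred on its median, and at 1205 loci at 12 h alone, with the rel- change higher at 19 and lower at 1186. After centring 331 loci differed at 12 h, 135 higher and 196 lower.

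The first pattern is that rel- libraries hold more signal than wild type libraries. Random error in the multipliers of single libraries is argued against, because both rel- libraries exceeded both wild type libraries at 9 of 9 times and the median shift of 2.70 exceeded the largest median difference between replicates, 0.67. A few loci taking most of the reads is argued against by a dusk ratio of 6.42 without the 20 highest loci. For the shift that loci share, a multiplier that differs systematically between the strains and an effect of the rel- genotype cannot be told apart: no standards are listed in the table used here, and the medians of R-prefixed and B-prefixed loci at dusk, 1.64 and 0.91, do not decide between them.

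The second pattern is the difference between the rel- replicates at 4 h and 8 h. If the multiplier of 1 library were the source, all loci would shift together, and the smaller shift of the median R-prefixed locus was 1.31. At 30 min the median R-prefixed locus of rel- differed by -1.63 (replicate 2 minus 1) where the sums differed 1.02-fold. The 4 h and 8 h value, under a condition added after it was first seen, therefore decides nothing. The factors of rel- replicates 1 and 2 were 3.06 and 5.02 at 4 h, with 7467772 and 8095809 reads. At 8 h the factors were 1.77 and 4.80, with 9776418 and 7065933 reads. The gap in the sums thus lies mainly in the factors, and whether a factor was in error stays open.

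The third pattern is that the strains respond differently to darkness. After centring 249 loci differed, 152 without the 12 h time. They cannot decide whether the multiplier is the whole cause, because the pseudocount was added before centring. A multiplier can thus still move low loci apart from the others, and centring removes the shift that loci share. The edgeR fit with TMM, given below, uses neither the multipliers nor the added pseudocount and also called loci. For the loci it called, this argues against the multiplier as the whole cause. Of the 249 loci, 67.1% had mean reads above the median of all loci. A mean over libraries does not show the reads at the times where the strains differed. Low read numbers therefore stay open. An effect of the genotype stays open, and the dependence of the count on single courses limits it.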

How the results depend on the processing

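Pseudocounts, the filter, limma without the trend or with robust moderation and a 2-fold minimum kept all 5 counts within 1.5 times, as did fewer libraries in the fit, a joint F-test or times from 1 h on where run. The split of the difference in response moved from 895 higher and 557 lower to 664 and 930 between the smaller and the larger pseudocount. That split is by the sign of the mean over the dark times, which itself passed at 14 loci in the main fit. The cause of the changes below was not tested unless stated. Centring on the median gave 1028, 1284, 158, 408 and 249 loci for wild type darkness, rel- darkness, the strains at dusk, the strains in darkness and the difference in response. Quantile normalization gave 1124, 185, 214 and 250 for the last 4. Added after seeing the data, edgeR with TMM gave 1103 for rel- darkness, 76 at dusk and 224 for the difference, and edgeR with the deposited factors kept every count within 1.5 times; 100% of values were whole reads, and it called 1902, 2333, 2443, 2655 and 1313 loci. The edgeR count for the strains in darkness is not reliable, since edgeR called 441 of 2573 unchanged simulated loci there. The difference in response gave 2311 with culture as a random effect, 91 on the course means and, as added settings, 99 without the 12 h time and 1560 without 4 h and 8 h. Leaving out libraries or courses gave 462 to 2106, 2175 to 2544, 2044 to 2485, 2390 to 2633 and 1 to 2110 loci; a lone sample is assumed to vary like the other groups. The dusk ratio of sums moved from 5.22 to 6.42 without the 20 highest loci, 6.02 as a median and 6.27 without R-prefixed loci, a setting added after seeing the data. With the same settings the ratio moved from 6.88 to 11.3, 13.5 and 9.77 at 1 h and from 1.53 to 2.17, 2.14 and 2.12 at 12 h. The sum at 12 h over that at dusk moved from 0.744 to 0.343, 0.238 and 0.433 in wild type and from 0.218 to 0.116, 0.0846 and 0.147 in rel-, so the size of the fall depends on the measure. The correlation of responses was 0.79 to 0.81 with quantile normalization, other pseudocounts or no filter, and centring cannot move it. The replicate block gave 1905, 2555, 2532, 2601 and 1941 loci, and 152 and 290 for the difference at 2 h and 4 h (354 and 528 with culture as a random effect). A block within each strain, added after seeing the data, gave 2380 for the difference. Same-numbered libraries deviated together within a strain (r across loci 0.13 to 0.79 in wild type and 0.32 to 0.89 in rel-) but not between strains (-0.24 to 0.24), so the numbers are shared labels across strains. Of 198 values for named tags under other settings, 196 kept their side of the threshold, 1 lost it and 1 gained it, and 0 past the threshold changed direction. The value of Synpcc7942_1377 in rel- darkness, not past it, turned to -0.11 with the smaller pseudocount. Gene lists were not run because 0 tags matched. The library with the fewest reads, wild type 12 h replicate 2, had 2001839, and a count of 0 in it allows a signal of up to 11.5.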

Other observations

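These tests were chosen after the results were seen. Loci with consecutive tag numbers had similar strain differences. Across 2594 pairs of consecutive tags, the centred rel- minus wild type difference at dusk had r = 0.32 across loci, above the highest of 1000 permutations, 0.063, and r fell to 0.18 at a distance of 2 tags and to 0.020 at 10. A candidate explanation is that neighbouring loci share transcripts. Tag order was taken as position, which the table does not state.

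A hypothesis is that the rel- response runs behind that of wild type, as the correlation of centred changes across loci may show. With both replicates, 5 of 8 rel- times were closest to an earlier wild type time and 0 to a later one. With libraries thinned to 2001839 reads, 6 of 8 were closest to an earlier one. The 5 min time had no earlier dark time to match, and the 12 h time no later one. In the replicate combination with the fewest, 4 of 8 were closest to an earlier time, under the 5 set for this hypothesis to hold, so it stays undecided.

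The median R-prefixed locus differed between replicates by 1.89 (log2, median over 9 times) in wild type, where the median of all loci differed by 0.28, and by 0.90 in rel-, where it was 0.41.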
